A study of Homo sapiens with 2 samples.

How the data were processed

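RNA from HSC2 and HSC3 cells was measured on 2 two-colour Agilent arrays, 1 per line, after transfection of 20 nM siRNA with Lipofectamine RNAiMAX. Per the labels, cells were grown in DMEM/F-12 with 10% FBS at 37 °C and 5% CO2, RNA was extracted with Trizol, and 500 ng of RNA was labelled, with Cy3 for the control siRNA and Cy5 for the siRNA against NTSR1. The labels give neither the siRNA sequences nor repeated cultures. The p-values over both lines therefore rest on the spread between these arrays, which may be technical, and on a variance pooled over genes. Both arrays were on 1 slide and were scanned in 1 session, per the file headers.

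The deposited array files hold the mean intensity of each spot and the median intensity of its local background in each dye, together with processed signals. Per the file headers, these were made with Agilent Feature Extraction 9.5.3.1, by spatial and multiplicative detrending and by dye normalization with a linear and a LOWESS step, with surrogate values for signals near background. The submitters' processing notes name version 9.1. The files also hold the deposited log10 ratio of the processed signals, Cy5 over Cy3, with its error. The deposited p-value of each log10 ratio comes from the software's error model for 1 spot and was not used here. The deposited series matrix holds the log10 ratio with its sign turned, Cy3 over Cy5: its correlation with the ratio of the array files was -0.999999 for each array, so its sign was turned back for the alternative that uses it. Which dye held which RNA was taken from the labels and not tested; the series matrix has the opposite orientation, for which no reason is given in the sources used here. The genome build of the probe coordinates is not given in the sources used here.

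Each array held 45015 spots, of which 43376 were not controls. Median signals of control and siNTSR1 channels were 70.5 and 122.3 intensity units in HSC2 and 67.2 and 127.3 in HSC3, over median local backgrounds of 41 and 46 and of 40 and 46. No spot was saturated. Intensities were corrected for background with the normexp method (offset 50) and normalized by loess within each array, with control spots at weight 0, in limma 3.58.1 under R 4.3.3, with matrixStats 1.5.0 and the package data.table (1.17.8); figures were drawn with matplotlib 3.10.9. Log2 ratios of Cy5 over Cy3 were computed here from the deposited intensity values. Spots marked as outliers by the software, 96 in HSC2 and 76 in HSC3, were left out, and spots of 1 probe were averaged. Of 41000 probes, 23434 were named by their RefSeq accession, 2317 by symbol and 1043 by a synonym, and 14206 kept the name in the file. Each gene was represented by its brightest probe over both arrays. A gene was counted in a line where this probe was well above background in at least 1 channel, by the software's mark.

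Within a line, genes at least 2-fold and 1.5-fold higher or lower were counted with no test. Over both lines, the log2 ratios were tested against 0 with limma (lmFit with an intercept and eBayes), with the Benjamini-Hochberg method and a threshold of 0.05. The fit had 1 residual degree of freedom, an estimated prior of 10.2 degrees of freedom and a prior SD of 0.116. Each SE over both lines is limma's moderated SE, in which the variance of a gene is drawn toward this prior. Agreement of the lines was described by correlation across genes and by overlaps against n1 × n2 / N for independent lists. The median of each gene list was set against 10000 random lists of the same size matched on deciles of mean log intensity, and a list was called displaced below percentile 2.5 or above 97.5. This was done in each line and for the mean over both lines, which is given for some lists. The members of each list were also adjusted alone. The lists were the neurotensin system; MAP kinase immediate early and feedback genes; NF-kB cytokines and chemokines; matrix proteases; basement membrane and integrins; epithelial-mesenchymal genes; the EGF family; angiogenic factors; S phase; G2 and M phase; p53 targets; interferon-stimulated genes; keratinocyte differentiation; basal keratinocyte genes; unfolded protein and integrated stress response; heat shock and oxidative stress; cholesterol synthesis; hypoxia and glycolysis; TGF-beta targets; apoptosis regulators; calcium and phospholipase C signalling; cytosolic ribosomal proteins; oxidative phosphorylation; and fibroblast, leukocyte, endothelial and epithelial markers. Levels in the lines were compared per channel after quantile normalization of mean log intensity between arrays.

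Groups, tests, gene lists, the rule for named genes and the alternatives were set before the data were examined, except the use of a second probe as an alternative, the tests of the siRNA duplex and of the bright probes, the comparison of spike-in transcripts and the number of simulations, which were chosen later. Genes are named if they belong to the neurotensin system or are CXCL8 or MMP1; are among the 12 highest or lowest in a line, in the called mean over both lines or in the difference in level; are up to 6 list members at least 1.5-fold the same way in both lines, or the highest or lowest member of a list in a line; or are at least 1.5-fold in opposite directions. Only genes with an official-looking symbol were named, and list members were also named in the comparison of levels. Exceptions are stated in the text. Some genes that this rule names are not reported here, though they count in every total and list.

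The alternatives were no background subtraction, an offset of 16, the processed signals, median centring, no background filter, a filter in both channels, the mean over probes, leaving out saturated spots, the series matrix, 1.5-fold in place of 2-fold, an intensity trend or robust eBayes, a threshold of 0.1, 1 line alone, list means, and random lists not matched on intensity. Second probes lay at least 100 bp from the brightest probe, and intervals came from 1000 bootstrap resamples of genes.

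The joint test was tested on simulated data, in 20 simulations of 19742 genes with 200 changed genes. It recovered 91.95% of the changes of 0.5 on the log2 scale and 100% of those of 1. The false share of its calls had a median of 9.91% and ranged from 1.60% to 29.2%, above the nominal 5% at its median. The data gave 3676 calls with means down to 0.25, so more genes and smaller changes than were simulated. The simulated recovery and false shares may therefore not hold for the reported calls. The simulated noise was independent between the arrays, and both lines had the same effect. A probe bias shared by both arrays was not simulated, so these shares do not cover false calls from such a bias. The prior degrees of freedom, estimated with 1 residual degree of freedom, came out between 8.50 and 95.2 for a true value of 10.2; how this bears on the false share was not tested. Of 200 simulated random lists, 2.5% were displaced, as were 100% of 50 lists of 20 genes with a planted shift of 0.3. Smaller shifts, such as several list medians reported here, and lists of co-regulated genes were not tried.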

Results

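Gene expression was measured after knockdown of NTSR1, a G protein-coupled receptor for the neuropeptide neurotensin, in HSC2 and HSC3. Both are established human cell lines derived from oral squamous cell carcinoma, a cancer of the head and neck. In each line, cells that received an siRNA against NTSR1 (siNTSR1) at 20 nM were compared with cells that received a control siRNA. RNA of the control cells was labelled with Cy3 and RNA of the siNTSR1 cells with Cy5, and both were hybridised to 1 two-colour Agilent array per line. The design therefore held 4 conditions on 2 arrays, with 1 array per line and no dye swap. Each array carried 41000 probes, of which 264 were spotted 10 times. In HSC2, 61.9% of the spots were well above background in the control channel and 68.8% in the siNTSR1 channel. The corresponding shares in HSC3 were 63.4% and 70.1%. Repeated spots differed little for probes with all 10 spots well above background in both channels (210 probes in HSC2, 213 in HSC3). Their median SD was 0.042 on the log2 scale in HSC2 and 0.043 in HSC3. Values are log2 ratios of siNTSR1 over control siRNA, so that a negative value means a lower level after knockdown. This orientation follows the labels, and exchanged dyes would turn the sign of each ratio. The number of arrays limits the precision, and values within 1 line have no replicate behind them.

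The first comparison asked how far NTSR1 itself was lowered. The NTSR1 probe that was well above background in both channels lay at a log2 ratio of -1.57 in HSC2, 2.97-fold lower with siNTSR1. In HSC3 it lay at -0.47, 1.39-fold lower. Over both lines NTSR1 fell, with a mean log2 ratio of -1.02 ± 0.18 (moderated SE, n = 2 lines). Its adjusted p by limma was 0.00371. The moderated SE draws on a variance pooled over genes and is smaller here than the 2 line values alone would give. SORT1, which encodes sortilin, another neurotensin receptor, stood at 0.33 in HSC2 and 0.17 in HSC3 and did not pass the test (limma adjusted p = 0.0552). Adjusted over the list alone, of the 2 measured genes of the neurotensin system 1 rose, SORT1, whose other probe was at 0.09 and -0.05, and 1 fell, NTSR1. NTS, the gene of neurotensin, and NTSR2 were not well above background in either channel of either line. The NTSR1 probe lies on chromosome 20 from position 60864245 to 60864305 in the coordinates of the array files, whose genome build is not given in the sources used here. NTSR1 was dim, at 160.1 intensity units over a local background of 39.5 in the HSC2 control channel and 61.98 over 39.0 in HSC3, so its ratio depended on the background correction and on the probes used, with -0.69 and -0.17 for the mean over its probes. In the scanner software's background-subtracted signals it was -2.85 in HSC2, with a software error of 0.34, and -2.05 in HSC3, with an error of 0.33. The other NTSR1 probe, not well above background in the control channel of either line, was on the opposite side, at 0.18 and 0.13, and at 2.0 and 2.02 in the software's signals.

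In HSC2 the genes furthest above control were CXCL14, an epithelial chemokine, at a log2 ratio of 2.19, and MMP13, a collagenase, at 1.94. NREP at 1.72, the receptor tyrosine kinase FGFR3 at 1.59 and the basal keratin KRT15 at 1.54 were also among the 12 highest, as were VAV3 at 1.49, the chemokine-scavenging receptor ACKR3 at 1.48, TNFSF10, the death ligand TRAIL, at 1.37 and MYLK, myosin light chain kinase, at 1.37. The furthest below control were the cholesteryl ester hydrolase gene NCEH1 at -2.31, the monoglyceride lipase gene MGLL at -1.63, NTSR1, COX6C, a subunit of cytochrome c oxidase, at -1.53 and the Mediator subunit gene MED8 at -1.49. Several secreted factors lay among the 12 lowest: the activin antagonist FST at -1.41, the interstitial collagenase MMP1 at -1.30, the Wnt inhibitor DKK1 at -1.30 and ESM1 at -1.26. PTGS2, which encodes cyclooxygenase-2, was also at -1.26. Of 20647 genes above background, 40 were at least 2-fold higher and 47 at least 2-fold lower with siNTSR1. At 1.5-fold, 396 were higher and 238 lower. The repeated spots of MMP1, TNFSF10 and PTGS2 had SDs of 0.038, 0.039 and 0.036, far below these ratios, which speaks to the array and not to the culture. The split between higher and lower genes depended on scaling: it was 498 against 183 with the software's processed signals and 1054 against 7 with median centring in place of the intensity-dependent (loess) correction, under which the median of the genes above background itself lay at 0.35.

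In HSC3 interferon-induced genes stood among the 12 highest: IFIT1 at a log2 ratio of 1.5, IFIT2 at 1.42, XAF1 at 1.40, MX2 at 1.38 and MX1 at 1.34. MYLK and ACKR3, both at 1.46, FGFR3 at 1.36 and the lymphotoxin gene LTB at 1.37 were of similar size. The furthest below control were COA6, a cytochrome c oxidase assembly factor, at -1.24, NCEH1 at -1.21, CCN2, the connective tissue growth factor, at -1.16 and SNRPA1, a U2 small nuclear ribonucleoprotein, at -1.15. LAT2 at -1.13 (second probe -0.28), MED8 at -1.04, CBFB at -0.94 (second probe 0.01), TMEM200A at -0.92 and COX6C at -0.91 followed. KLC3 at 1.59, SLC35E4 at 1.43 and VHL at 1.34 were also among the highest, but they belonged to a set of 12 very bright probes, chosen after their values were seen for similar ratios. The other probe of KLC3 was at -0.10 and that of VHL at -0.13, and the bright probe named VHL has a file coordinate on chromosome 9, whereas VHL lies on chromosome 3. Of 21048 genes above background, 48 were at least 2-fold higher and 7 at least 2-fold lower; at 1.5-fold the counts were 439 and 114. The 2-fold counts were 574 and 112 with the processed signals and 1184 and 1 with median centring, where the median gene lay at 0.36.

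The next comparison asked which genes changed in their mean over both lines, with each line as 1 replicate. A gene far from 0 in only 1 line could be called, as LTB and FST were. The gene that rose most was CXCL14, with a mean log2 ratio of 1.53 ± 0.21 (moderated SE, n = 2 lines). FGFR3 followed with 1.47 ± 0.09, then ACKR3 with 1.47 ± 0.08, MYLK with 1.42 ± 0.08 and KRT15 with 1.37 ± 0.09. XAF1, IFIT2, NREP, KLC3, IFIT1, MMP13 and GPNMB completed the 12 highest, with means from 1.36 down to 1.18. The genes that fell most were NCEH1, at -1.76 ± 0.18, MED8 at -1.26 ± 0.10, COX6C at -1.22 ± 0.12, TMEM200A at -1.12 ± 0.10 and COA6 at -1.12 ± 0.09. MGLL, CCN2, TSPAN6, NTSR1, SNRPA1, the cytokine subunit gene IL23A and MMP1 followed, with means from -1.12 to -0.95. CXCL8, the neutrophil chemokine interleukin-8, fell by 0.59 on the log2 scale (SE 0.08, limma adjusted p = 0.000881), and MMP1 fell by 0.95 (SE 0.13, limma adjusted p = 0.000997). In limma, 2411 genes rose and 1265 fell among 19742 tested at a Benjamini-Hochberg adjusted p under 0.05, and the smallest called mean was 0.25 on the log2 scale. A second probe of the same gene gave 1.36 and 1.34 in HSC2 and HSC3 for MYLK, 0.54 and 0.26 for FGFR3, 0.55 and 0.67 for XAF1, -1.16 and -0.81 for TMEM200A and -0.25 and -0.41 for MED8, but 0.33 and 0.01 for GPNMB; in 263 of 1266 called genes with several measured probes, probes had opposite signs. With 1 residual degree of freedom against a prior of 10.2, these p-values rested mainly on a variance pooled over genes. The spread of the gene itself between the 2 arrays weighed less. With the same dye orientation on both arrays, they could not separate the siRNA from a dye effect of the probe. The count fell to 444 higher and 179 lower with the processed signals, 396 of them called the same way in both analyses, and was 11620 higher and 1815 lower with median centring, which left MMP1 at a mean of 0.02 and CXCL8 at -0.27, both without a call. FST lost its call or changed sign in 6 alternatives, and LTB lost its call in 5. MGLL lost its call in 3 alternatives, and NREP, KLC3 and TMEM200A lost theirs in 2 each.

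**Figure D1:**
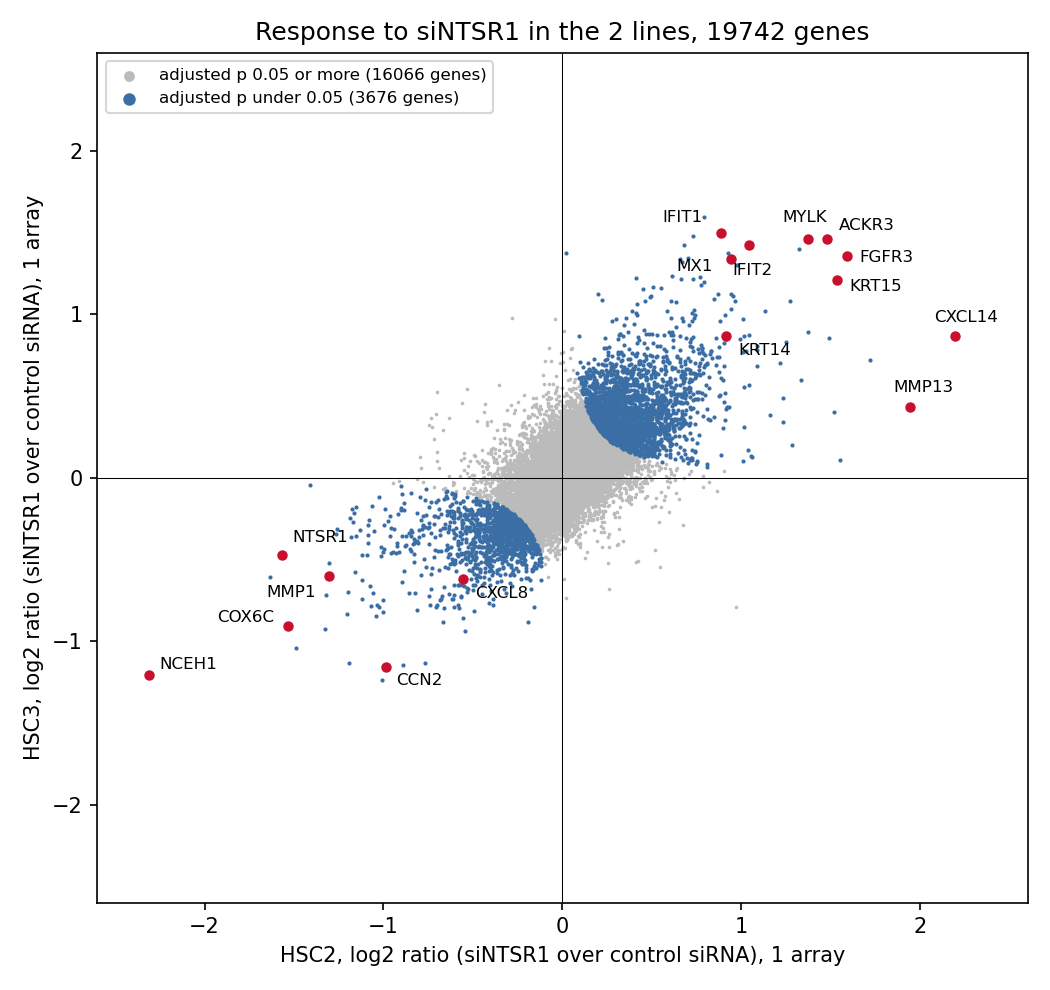
Log2 ratio of siNTSR1 over control siRNA in HSC2 (horizontal axis) against HSC3 (vertical axis), 1 point per gene for 19742 genes and 1 array per line. Blue points are the 3676 genes with a limma adjusted p under 0.05, grey points the other 16066 genes, and red points named genes; NCEH1 lies furthest left at -2.31 and -1.21, and FGFR3, ACKR3 and MYLK lie above 1.3 in both lines.

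Gene lists fixed before the data were examined were then described, by the percentile of their median among 10000 random lists of matched intensity in each line and by the number of members called over both lines. Genes downstream of MAP kinase signalling were lower as a list in both lines. Their median log2 ratio was -0.25 in HSC2 (percentile 0) and -0.08 in HSC3 (percentile 1.85), and 9 of 23 measured members fell while 2 rose. With the test adjusted over the list alone, 10 fell and 2 rose. The members that fell included the cell cycle gene CCND1, at -1.06 in HSC2 and -0.70 in HSC3, the ERK phosphatase gene DUSP6 at -1.09 and -0.35, and the ETS factor gene ETV4 at -0.56 and -0.73. The AP-1 genes JUN, at 0.28 and 0.45, and JUNB, at 0.69 and 0.23, rose, although the second probe of JUNB was at 0.39 and -0.07. Of 9 measured genes of the EGF family, 3 fell and none rose, and the same held adjusted over the list alone. These were the ligand genes HBEGF, at -1.01 and -0.42, TGFA, at -1.0 and -0.45, and EREG, the last named after its values were seen; the list median was at percentile 66.2 in HSC2 and 40.6 in HSC3, although in HSC2 it was displaced lower in 4 of 10 alternatives, with a list mean of -0.30 at percentile 0.04. With the processed signals 4 MAP kinase members were called lower and none higher, and none of the EGF family was called. The MAP kinase list in HSC3 was no longer displaced without background subtraction (percentile 2.74) or with the filter in both channels (2.70). Under median centring its medians were -0.01 in HSC2 and 0.28 in HSC3, or -0.36 and -0.08 relative to the median gene.

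Inflammatory cytokines and chemokines driven by NF-kB were also lower as a list, with a median of -0.26 in HSC2 (percentile 0) and -0.13 in HSC3 (percentile 0.2). Of 20 members measured in both lines 7 fell and 1 rose, or 8 and 1 adjusted over the list alone. PTGS2 fell, at -1.26 in HSC2 and -0.31 in HSC3, together with CXCL8, at -0.56 and -0.62. NFKBIA, which encodes the NF-kB inhibitor IkB-alpha, rose, at 0.25 and 0.47. The processed signals left CXCL8 as the 1 member called lower, with the list at percentile 3.79 in HSC3. Under median centring the list median was 0.00 in HSC2 and 0.42 in HSC3, which is -0.35 and 0.06 relative to the median gene, at percentile 15.8 in HSC3. The mean of the list in HSC3 was -0.04, at percentile 5.95.

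Matrix proteases and invasion genes moved both ways. Of 21 measured members 4 rose and 4 fell, or 8 and 5 adjusted over the list alone. MMP13, at 1.94 in HSC2 and 0.44 in HSC3, and the gelatinase gene MMP9, at 0.41 and 1.22 rose. MMP1, at -1.30 and -0.60, was among those that fell. PLAU, a list member named after its values were seen, was at 0.58 and 1.02, on 1 of the 12 very bright probes described above. Of the proteases 3 were called higher and 1 lower with the processed signals. The list median lay at percentile 96.6 in HSC2 and 81.5 in HSC3, and 5 of 10 alternatives displaced it higher in HSC2. For the mean over both lines the list was displaced higher, with a median of 0.19 at percentile 99.8. Among 15 angiogenic and growth factors 4 rose and 2 fell, with the same counts adjusted over the list alone; FGF2 fell, at -0.81 in both lines, and PDGFA, at 0.41 and 0.39, rose. This list was at percentiles 12.1 and 86.6; with the processed signals its HSC2 median was -0.26 at percentile 0.15, and none was called higher and 1 lower.

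Interferon-stimulated genes were higher as a list in both lines, with a median of 0.62 in HSC2 and 0.69 in HSC3, above all 10000 random lists in each. Of 26 measured members 24 rose and none fell, with the same counts adjusted over the list alone. Beside IFIT1 and IFIT2 they included the antiviral GTPase genes MX1, at 0.94 and 1.34, and MX2, at 0.93 and 1.38, as well as IFI44L at 0.95 and 1.13 and USP18 at 0.94 and 1.03. IFNB1, the gene of interferon beta, was at 0.11 and 0.01, with the control channel not well above background, and had a limma adjusted p of 0.69. With the processed signals 16 members were called higher. In the 8 genes with a second probe, that probe was above 0 in both lines in 8 of 8 cases, with a median of 0.48 against 0.68 for the brightest probe.

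Genes of the list named basal keratinocyte genes were higher as a list in both lines. Their median was 0.55 in HSC2 and 0.67 in HSC3, at percentile 100 in each, and 8 of 11 members rose, or 9 adjusted over the list alone. KRT15 was at 1.54 and 1.21, KRT14 at 0.92 and 0.87, KRT17 at 0.78 and 0.78 and KRT16 at 0.59 and 0.72. The nerve growth factor receptor gene NGFR was lowest, at -0.17 and -0.15, without a call. Genes of keratinocyte differentiation were near the edge of the random lists, at percentile 98.1 in HSC2 and 97.3 in HSC3, and were displaced in 3 of 10 alternatives in HSC2 and 6 in HSC3. For the mean over both lines they were not displaced, at percentile 90.9. Of 20 members 6 rose and 2 fell, the same adjusted over the list alone. KRT1, a keratin of differentiating layers, rose, at 1.25 and 0.83. Among 8 epithelial markers 4 rose and 2 fell, the latter being EPCAM, at -0.12 and -0.51, and KRT8, at -0.19 and -0.37. Under median centring KRT8 and EPCAM lay above 0, at means of 0.37 and 0.34, close to the median gene. The processed signals called 3 basal keratinocyte genes, 3 differentiation genes and 1 epithelial marker higher and none of these lower. The epithelial markers were at percentiles 92.6 and 99.9.

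Replication genes were slightly lower. The S phase list had medians of -0.11 in HSC2 (percentile 1.36) and -0.20 in HSC3 (percentile 0.01); 6 of 26 members fell and none rose, also adjusted over the list alone. CDC45, a component of the replicative helicase, was at -0.41 and -0.49 and GINS1 at -0.42 and -0.21. The list of G2 and M phase genes was inside the range of random lists in both lines, at percentiles 41.6 and 3.03, with 1 gene called higher, TOP2A, and 3 lower, among them CDK1 and BUB1, which lay at means of 0.39 and 0.33 under median centring, but none adjusted over the list alone. With the processed signals no member of either list was called and the S phase list was at percentile 5.91 in HSC2; with median centring its medians were 0.57 and 0.42, above the median gene, at percentiles 6.27 and 0.01.

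**Figure D2:**
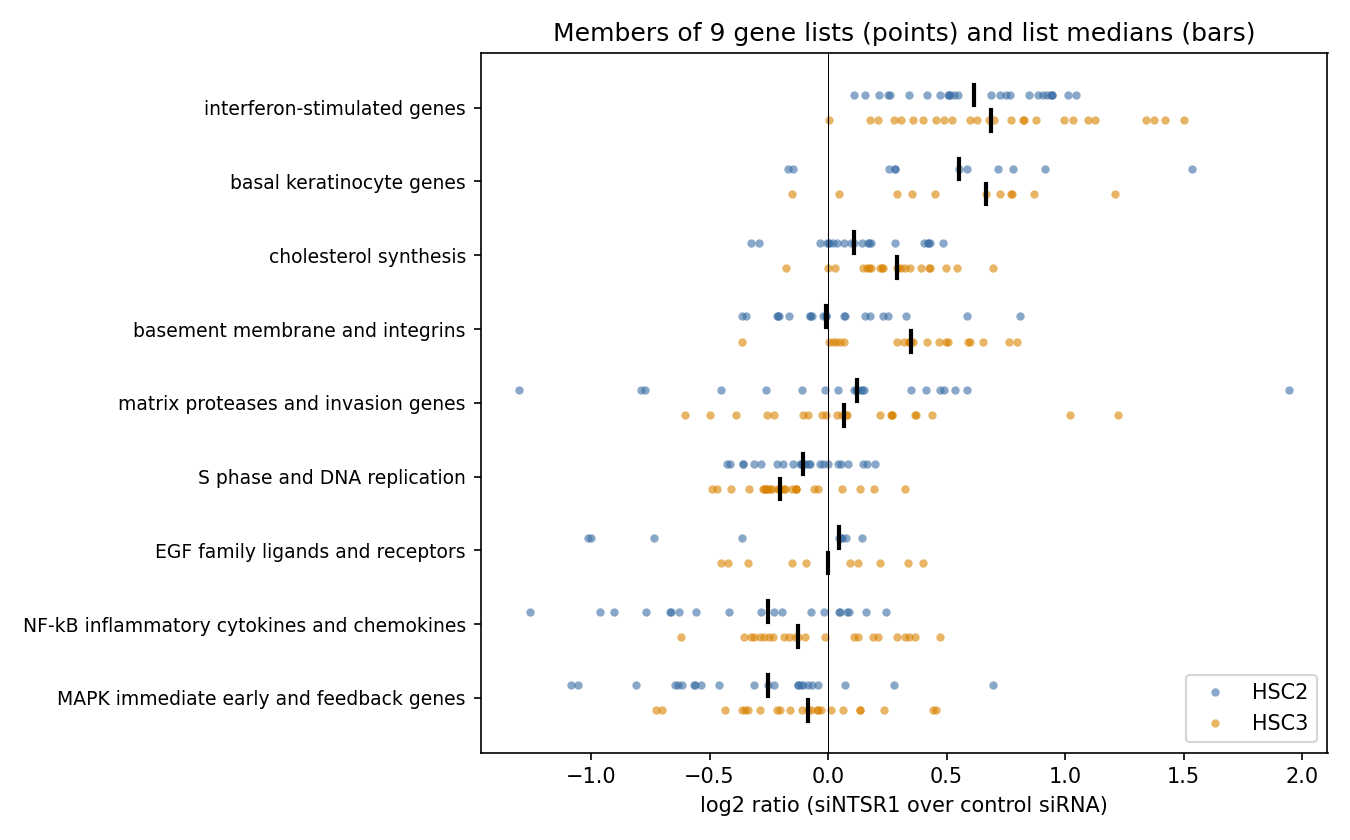
Log2 ratio of siNTSR1 over control siRNA (horizontal axis) for the members of 9 gene lists that were above background, HSC2 in blue and HSC3 in orange, with a black bar at each list median. Interferon-stimulated genes have medians of 0.62 and 0.69 and basal keratinocyte genes of 0.55 and 0.67, while the MAP kinase list has -0.25 and -0.08 and the NF-kB list -0.26 and -0.13; under median centring the MAP kinase median in HSC3 (0.28), the NF-kB medians (0.00 and 0.42) and the S phase medians (0.57 and 0.42) lie above 0.

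Further lists gave smaller or mixed changes. Among 20 targets of p53, 6 rose and 4 fell, or 9 and 5 adjusted over the list alone: TP53INP1 rose, at 0.66 in HSC2 and 0.63 in HSC3, and the death receptor gene FAS fell, at -0.70 and -0.78. Their median was 0.14 at percentile 98.4 in HSC2 and 0.15 at percentile 96.9 in HSC3, and 5 of 10 alternatives displaced the list in HSC2 and 1 in HSC3. The mean over both lines put these targets at percentile 98.6. With the processed signals 1 was called higher and 2 lower. Among 21 genes of cholesterol synthesis 7 rose and none fell, or 8 and none adjusted over the list alone, at percentiles 94.6 and 99.98. For the mean over both lines the cholesterol list was at percentile 99.3. HMGCS1, at 0.43 and 0.69, and MSMO1, at 0.49 and 0.54, rose, although the second probe of HMGCS1 was at -0.21 and 0.23 and none of the list was called with the processed signals. Of 16 epithelial-mesenchymal genes 3 rose, with the desmosome gene DSP at 0.48 and 0.70 and the tight junction gene CLDN1 at 0.42 and 0.86 (second probe 0.08 and 0.42), and 3 fell, with the same counts adjusted over the list alone; the list was at percentiles 18.5 and 51.8, and with the processed signals none was called higher and 1 lower. Among markers of other cell types, 1 of 5 fibroblast genes rose, COL1A1, and none fell, with medians of 0.26 at percentile 99.5 in HSC2 and 0.09 at percentile 78.6 in HSC3. Of 8 leukocyte genes 4 rose and none fell, among them CSF1R at 0.09 and 0.87 and CD68 at 0.46 and 0.28, with medians of 0.06 at percentile 83.3 in HSC2 and 0.25 at percentile 99.9 in HSC3, or 94.8 with the processed signals, where 1 was called higher. For the mean over both lines the leukocyte genes were at percentile 99.97. The 1 endothelial gene measured in both lines, VWF, was not called. The marker counts were the same adjusted over the list alone, also for the epithelial markers.

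The ratios of the 2 lines were then compared across genes. Pearson's r was 0.66 and Spearman's rho 0.63 over 19742 genes, which are not independent replicates, and 71.6% of the genes had the same sign. At 2-fold, 8 genes were higher in both lines against 0.09 for independent lists, and 4 were lower in both against 0.017. At 1.5-fold the counts were 159 higher against 8.56 and 48 lower against 1.32. Genes such as FGFR3, ACKR3 and MYLK were higher by similar amounts in both lines, and FGF2, FAS and CCN2 were lower by similar amounts. Because both arrays had the same dye orientation, probes of different parts of the same gene were also compared. For 4500 genes with a second probe at least 100 bp away, the same probe correlated between the arrays with r = 0.68, and different probes of a gene with r = 0.39 (95% bootstrap interval 0.36 to 0.41). Of 785 such genes called higher, the second probe had the same sign in 82.0% and was itself called in 28.8%; of 322 called lower these shares were 87.6% and 43.8%. The correlation was 0.58 with the processed signals and 0.82 with median centring.

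Differences between the lines in the response could be given only as values, since each line had 1 array. MMP13 was at 1.94 in HSC2 and 0.44 in HSC3, CXCL14 at 2.19 and 0.86 and FST at -1.41 and -0.04. LTB was at 0.02 in HSC2 and 1.37 in HSC3, and MMP9 at 0.41 and 1.22. BNIP3, a mitophagy gene induced by hypoxia, was at -0.70 and 0.53, and was not called over both lines. KRT18 was at -0.74 and 0.32 without a call, but its second probe was lower in both lines, at -0.92 and -0.30 (limma adjusted p = 0.0071). The hypoxia and glycolysis list was at percentile 16.9 in HSC2, with a median of -0.04, and at percentile 100 in HSC3, with a median of 0.32. For the mean over both lines it was not displaced, at percentile 84. Of 19 members 5 rose and none fell, the same adjusted over the list alone, with NDRG1 at 0.66 and 0.87. Basement membrane and integrin genes were at percentile 37.6 in HSC2 and 100 in HSC3, with medians of -0.01 and 0.35. The mean over both lines put them at percentile 99.4. Of 21 members 6 rose and none fell, or 6 and 1 adjusted over the list alone; ITGAV rose, at 0.59 in both lines, with a second probe at 0.06 and 0.04. No basement membrane gene was called with the processed signals, and 1 hypoxia gene was called higher. The reverse order was seen for TGF-beta targets, with a median of 0.32 at percentile 100 in HSC2 and of 0.07 at percentile 77.2 in HSC3. In the mean over both lines these targets were at percentile 99.9. Of 16 members 6 rose and 2 fell, or 8 and 2 adjusted over the list alone: COL1A1, at 1.23 and 0.34, and TGFBI, at 0.81 and 0.70, rose, and CCN1, at -1.09 and -0.47, and CCN2, at -0.99 and -1.16, fell. Of these targets 1 was called higher and 1 lower with the processed signals. CXCL14 and MMP13 differed less with the processed signals, at 2.35 and 2.63 and at 2.23 and 1.87. In 1 case a gene was at least 1.5-fold higher in HSC2 and at least 1.5-fold lower in HSC3, and it carried a clone name (BC054888, at 0.97 and -0.79), singled out after its values were seen; the processed signals gave 27 genes in opposite directions, in either order.

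The lines also differed in the level of many genes, compared separately in the control and the siNTSR1 channels. The simple-epithelium keratin gene KRT19 was at least 289-fold higher in HSC3 in the control channel, where HSC2 was not well above background, and 408-fold higher in the siNTSR1 channel. KRT8 was 29.9-fold and 26.3-fold higher in HSC3, the intermediate filament gene VIM 21.1-fold and 33.1-fold, the cytokine gene TNF 25.3-fold and 30.1-fold, and the metalloproteinase gene ADAM8 26.0-fold and 45.3-fold. In HSC2, the basement membrane collagen gene COL4A2 was 108-fold higher in the control channel and 112-fold higher in the siNTSR1 channel, and COL4A1 11.4-fold and 19.0-fold higher. RASIP1, at 53.4-fold and 33.4-fold, and the inhibitors of differentiation ID1, at 16.1-fold and 21.0-fold, and ID3, at 13.1-fold and 20.0-fold, were also higher in HSC2, as was EYA2, at least 23.5-fold and at least 33.7-fold. Among list members, MMP3 and CXCL2 were higher in HSC3, by 4.43 and 3.72 on the log2 scale in the control channel, whereas SOX2, KRT1 and IFI44L were lower in HSC3, with HSC3 minus HSC2 at -2.95, -3.09 and -2.82. Over the genes above background in both lines, 665 were at least 2-fold higher in HSC3 in both channels and 835 at least 2-fold higher in HSC2. The channel differences of the 2 conditions correlated across genes with r = 0.96. The "at least" values set the brighter line against the higher of the dim signal and the lowest signal well above background, and all of these levels rest on 1 array per line; the counts were 1470 and 1683 with the processed signals.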

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

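The comparison of spike-in transcripts between the arrays was chosen after the values were seen, as was the naming of BC054888. Control transcripts added to the labelling reactions, which the comparisons do not use, differed between the arrays. For 10 spike-in transcripts the log2 ratio was 0.44 higher in HSC2 than in HSC3 on average (SD 0.085 across transcripts, range 0.25 to 0.56), and the cause was not tested. Against the nominal ratios of these transcripts, the file headers give an intercept of 1.44-fold in HSC2 and 1.06-fold in HSC3, with slopes of 0.909 and 0.890. The spike-in values came from the deposited ratios of the processed signals, whereas the list medians came from the ratios computed here with another normalization. How this offset bears on differences between the lines of similar size, as in the TGF-beta medians (0.32 and 0.07), was not tested. A difference between the lines stood out in BC054888, a clone name, which was at 0.97 in HSC2 and -0.79 in HSC3, a difference of -1.76 that was not tested because each line had 1 array.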

How the results depend on the processing

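The second-probe alternative was chosen after seeing the data, and the other alternatives were planned. No paired analysis was possible because each line had 1 array, in which siNTSR1 and control already share a spot. Leaving out 1 line left no residual degrees of freedom, so the other line then gives a value with no test. Leaving out saturated spots changed nothing, as none was saturated. Each value was labelled by its class and not by its size. The class was at least 1.5-fold or not in 1 line, called or not over both lines, and displaced or not for lists. A value labelled the same kept its class, but its size could change, as could its sign where it lay within these limits. For named genes, 2252 values in 1 line were labelled the same, 121 stronger, 59 weaker and 7 reversed. Over both lines 999 were the same, 28 stronger, 141 weaker and 13 reversed. For lists 488 were the same, 33 stronger, 29 weaker and 10 reversed. These totals include the setting without saturated spots. Over the other 10 alternatives, interferon-stimulated and basal keratinocyte genes were displaced the same way in both lines in 10, MAP kinase genes in 8, S phase in 7, NF-kB in 6 and ribosomal proteins in 5. Counted in HSC2 regardless of HSC3, TGF-beta targets were displaced higher in 10 and fibroblast markers in 9. There, p53 targets and proteases were displaced higher in 5 each and differentiation genes in 3. Oxidative phosphorylation was displaced lower in HSC2 in 6, the stress response in 3 and the EGF family and angiogenic factors in 4 each. Counted in HSC3 regardless of HSC2, the basement membrane, hypoxia, cholesterol and epithelial marker lists were displaced higher in 10 each. Leukocyte markers were displaced higher there in 8, differentiation genes in 6 and p53 targets in 1. Oxidative phosphorylation was displaced lower in HSC3 in 5, and the stress response and G2 and M phase in 1 each. Dim genes are limited by the background, as the offset shows below. Except where stated, the cause was not tested.

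With the 1.5-fold limit, which admits more genes by construction, HSC2 had 396 higher and 238 lower and HSC3 439 and 114, with 159 higher and 48 lower in both lines. With an offset of 16, NTSR1 was -2.13 in HSC2 and -0.86 in HSC3, HSC2 had 64 genes 2-fold higher, HSC3 12 lower, r was 0.64, and 19 genes were higher and 8 lower in both lines. With the mean over probes NTSR1 was -0.69 in HSC2 and -0.17 in HSC3, r was 0.65 and 5 genes were higher in both lines. Without a filter r was 0.63, and with the filter in both channels 0.67. Second probes, available for 4500 genes, gave 427 higher and 374 lower, where the main analysis called 785 of the same genes higher and 322 lower.

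With the processed signals NTSR1 was -2.85 and -2.05, HSC2 had 498 higher and 183 lower, HSC3 574 and 112, and both lines 444 and 179; r was 0.58, with 113 higher and 31 lower in both, 27 opposite genes, 1683 genes higher in level in HSC2 and 1470 in HSC3, and 3 lists displaced in both lines. With the series matrix these were -2.85 and -2.05, 495 and 181, 573 and 110, 393 and 156, 0.58, 112 and 31, 27 opposite genes and 3 lists. The ribosomal median turned to -0.013 in HSC2 and -0.037 in HSC3 in both of these.

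Median centring leaves the intensity-dependent dye difference in place: the median gene lay at 0.35 in HSC2 and 0.36 in HSC3. HSC2 then had 1054 higher and 7 lower, HSC3 1184 and 1, both lines 11620 higher; r was 0.82, with 593 higher and 0 lower in both, and 2 opposite genes. List medians of 1 line changed sign in 19 cases, most of them for lists not displaced in the main analysis. Counting only displaced lists, called genes and genes at least 1.5-fold in a line, 26 values turned, and 20 of these still lay below the median gene. Displaced list medians turned for MAP kinase (HSC3 0.28), NF-kB (HSC2 0.0019, HSC3 0.42), S phase (0.57 and 0.42) and oxidative phosphorylation (HSC2 0.61). In HSC3 MMP1 was 0.35 and MGLL 0.046; in HSC2 PNP was 0.13, TRIB3 0.23, SRXN1 0.025, BNIP3 0.0035 and KRT18 0.11. Means over both lines turned for MMP1 (0.017), FST (0.050), AKR1C3 (0.11), PNP (0.013), GSTO1 (0.040), EPCAM (0.34), CDC45 (0.30), BUB1 (0.33), CDK1 (0.39), TRIB3 (0.33), HERPUD1 (0.20), SRXN1 (0.12) and KRT8 (0.37).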

Other observations

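The tests of the siRNA duplex and of the bright probes were chosen after their results were seen. Several lists not yet described moved little or both ways. In the unfolded protein and integrated stress response 1 of 22 genes rose and 4 fell, the same adjusted over the list alone, at percentiles 8.43 in HSC2 and 27.6 in HSC3, or 1.23 and 1.15 with median centring: DDIT4, an inhibitor of mTOR signalling, rose, at 0.42 and 1.06, and TRIB3, at -0.60 and -0.31, and HERPUD1, at -0.54 and -0.45, fell, whereas both had means above 0 with median centring (0.33 and 0.20). Of 17 heat shock and oxidative stress genes 2 rose and 4 fell, the same adjusted over the list alone, at percentiles 74.5 and 48.1. The small heat shock protein gene HSPB1 rose, at 0.82 and 0.62, and the cystine transporter gene SLC7A11 fell, at -0.49 and -0.81. Of 16 apoptosis regulators 3 rose and 2 fell, or 4 and 3 adjusted over the list alone, at percentiles 39.7 and 38.4, with TNFSF10 at 1.37 and 0.89 and the survival gene BCL2L1 at -0.50 and -0.45 (second probe -0.19 and -0.13). Of 14 genes of calcium and phospholipase C signalling, the pathway to which NTSR1 couples, 1 rose, PRKCA, whose second probe was at 0.13 and -0.02, and 2 fell, among them RGS4, or 2 and 2 adjusted over the list alone, at percentiles 16.6 and 27.1. With the processed signals none of the stress response genes was called, 1 heat shock gene was called higher, 1 apoptosis regulator higher and 1 lower, and 1 calcium signalling gene lower.

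Of 24 cytosolic ribosomal protein genes 8 rose and 1 fell, or 11 and 2 adjusted over the list alone, at percentiles 98.2 in HSC2 and 99.3 in HSC3, with medians of 0.14 and 0.21 that turned to -0.01 and -0.04 with the processed signals. RPS2 was at 0.52 and 0.56, with a second probe at 0.22 and 0.23 and probes of opposite sign among its 6. Of 19 genes of oxidative phosphorylation none rose and 4 fell, the same adjusted over the list alone, at percentiles 1.48 and 3.62. For the mean over both lines the list was at percentile 1.62. COX6C was at -1.53 and -0.91; the list medians were 0.61 and 0.54 with median centring, at percentiles 3.14 and 2.90. No ribosomal gene was called with the processed signals, and 1 gene of oxidative phosphorylation was called lower.

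The ratios of the lines correlated across genes, and the arrays shared their dye orientation. A dye bias of single probes as the whole cause was argued against, since different probes of a gene still correlated between the arrays with r = 0.386. Such effects as part of the cause were in line with the drop of 0.292 (95% bootstrap interval 0.273 to 0.312) from the correlation of the same probe. The second probes were dimmer, but the same-probe correlation is the average for brightest and second probes. The covariance between the arrays fell too, from 0.0380 for the same probe to 0.0206 for different probes, with 54.3% kept. Noise that is independent between spots does not lower a covariance. For these 4500 genes the values therefore argue against such noise as the source of the drop. Whether the dimness of second probes added to it in another way was not tested. A dye effect shared by all probes of a transcript, or an effect of the siRNA on other transcripts, was not tested.

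Interferon-stimulated genes were higher in both lines. A dye bias of single probes was argued against, since second probes of 8 of these genes had a median of 0.48 against 0.68 for the brightest probes. An innate response to the siRNA duplex and a response to the loss of NTSR1 cannot be told apart, because 1 siRNA against NTSR1 was measured. IFNB1, at a mean of 0.057 with its control channel near background, does not decide between them. A further siRNA of another sequence would be needed.

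A set of 12 probes, among them those of KLC3, SLC35E4 and VHL, was chosen after the values were seen, by a mean log2 brightness above 14, a ratio from 0.5 to 0.8 in HSC2 and a ratio of at least 1 in HSC3, so the likeness of their ratios is partly built in. After normalization, 385 other probes of like brightness had a median of 0.20 in HSC3, 5 of them at 1 or more. The loess step draws ratios at each intensity toward 0. This median therefore could not decide whether all probes of that brightness shared a ratio before normalization. Signal from 1 abundant transcript on probes named for other genes is a candidate explanation that stays open: in 5 of 6 genes with another probe, that probe was at least 3 log2 units dimmer with a ratio at least 0.5 lower, but choosing by ratio favours that outcome. The exception was ACTB, named after its values were seen. Its other probe was also bright, at a mean log2 brightness of 15.06, and lay at 0.35 in HSC2 and 0.52 in HSC3. For the 214 probes of like brightness with another probe of the gene, 22.4% of the other probes were at least 3 log2 units dimmer. Probe sequences were not used here, and no biological explanation was tested.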
